A study of Glycine max with 6 samples.

How the data were processed

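Total RNA from soybean (Glycine max) seed tissue was measured on 6 Affymetrix soybean arrays, which also carry probe sets for the pathogens Phytophthora sojae and Heterodera glycines. Per the labels, 2 arrays held wild type material and 4 held material of plants carrying an RNA interference construct against oleosin. The 4 came from 2 biological replicates with 2 technical arrays each. The titles were used for grouping. The descriptions of both arrays of transgenic replicate 1 call them controls, against their titles and source names. The labels do not say whether the wild type arrays are biological or technical replicates.

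The deposited table holds 1 linear intensity per probe set and array. The software and scaling method are not given in the sources used here. A 2% trimmed mean of the intensity over all 61170 probe sets was 500 on every array, so the values had been scaled to a common mean before deposit. The medians of the soybean probe sets lay within 0.09 log2 units of each other, under the limit of 0.2 set in advance, and no further scaling was applied. Analysis used log2(intensity + 16), a scale that understates the fold of dim probe sets.

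Of the probe sets, 37593 were soybean, 23350 pathogen, 92 ribosomal RNA and 135 control. A soybean probe set was tested when its mean over the 4 biological samples exceeded the 95th percentile of that mean over the pathogen probe sets, 6.04 on the log2 scale or an intensity of 49.9. This left 29574. A group in which both samples, as averaged log2 values, lay at or under that cutoff has only a bound, and its fold is given as "at least", computed against the cutoff. Single technical arrays of HPS, AGL1L, GA2OX6, LOXB1 and LOC100306605 lay slightly above it, at up to 57.0. For Ep and MS single arrays reached 117 and 85.5, and no bound is given. The number of arrays limits the precision.

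Gene symbols came from GEO's platform annotation of the array, an old table, with symbols looked up through gene identifiers in the RefSeq gene table of assembly Glycine_max_v4.0. One gene was given for 8677 probe sets, several for 370, and none for 28546 soybean probe sets. Of the 8677, 8652 had an identifier in the RefSeq table. No gene was named from a probe set with several genes, and coordinates were not used. Of several probe sets of a gene the one with the highest mean stood for it, giving 5415 genes.

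Technical arrays were averaged, and the 2 transgenic samples were compared with the 2 wild type samples in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with a trend), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The fit had 2 residual degrees of freedom. The p-values measure the spread between these samples, which for wild type may be technical. The transgenic samples were also compared with each other over their 4 arrays, a test of those samples only, whose error is technical. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 22 lists with at least 3 genes. The estimates ranged over the lists from -0.020 to 0.9997. With an estimate camera also took its p from the 2 residual degrees of freedom. Its p thus rose even in lists whose estimate was near or under 0.01.

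Groups, tests, alternatives, list themes and the rule for named genes were fixed before the data were examined. The rule took every oleosin probe set, the 10 genes with the largest rise and the 10 with the largest fall past the threshold whose transgenic samples both lay outside the wild type range, up to 4 genes with the smallest p in each list, and the 5 largest differences each way between the transgenic samples. The lists had been written as words to be found in gene descriptions. The annotation holds symbols only, so members were assigned from symbols by hand after the annotation was seen and before soybean gene values were. The families GST, WRKY, MYB, NAC, bZIP, aquaporin and GASA were added at that point. No member was found for other oil body proteins or small RNA silencing, and these lists were not tested. Genes with a descriptive symbol that stand outside the rule were chosen after their values were seen, and are marked so. Tests of explanations in the closing section were all written after exploratory values had been seen.

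The fit was tested on simulated data for the 29574 probe sets, 2 samples against 2. The simulation used their real means and limma's moderated spreads, with independent normal noise of equal spread in both groups. In the data the median SD was 0.11 in wild type and 0.27 between transgenic samples, and genes of several lists were correlated. The simulated rates may therefore not hold for the data. The fit called 4 of 67 probe sets changed by 1 log2 unit, 27 of 67 changed by 2 and 59 of 66 changed by 4, with 12 false calls. On 5415 simulated genes camera found a list of 20 genes shifted by 1 log2 unit and did not call a list of 20 that were not shifted. Alternatives covered the treatment of technical arrays, scaling, pseudocount, filter, variance model, a replicate block, each sample left out and each technical array alone. An alternative with the wild type arrays averaged to 1 sample was added after seeing the data.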

Results

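Oleosins coat the oil bodies of seeds, and the series addressed what changes in soybean cotyledon when oleosin is suppressed by RNA interference. Signals of 37593 soybean probe sets were available for 2 wild type arrays and for 2 transgenic biological samples with 2 technical arrays each. Between 72.0% and 76.4% of soybean probe sets on each array were brighter than the 95th percentile of the pathogen probe sets of the same array. The median soybean signal lay between 271 and 288.

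The wild type arrays differed from each other about as much as technical arrays did. The median SD over 29574 probe sets was 0.11 log2 units between the wild type arrays, 0.11 and 0.10 between the technical arrays of transgenic samples 1 and 2, and 0.27 between the transgenic biological samples. No test was made of these spreads. The ratio of 3′ to 5′ control signals, a sign of RNA quality, was 3.29 and 2.95 for the SucBP control in wild type, 4.96 and 4.22 in transgenic sample 1, and 9.09 and 9.33 in sample 2. For actin it was 2.01 and 1.98, then 1.72 and 1.76, then 2.43 and 2.65. For the P450 control it was highest in wild type, 4.92 and 4.06, against 3.44 and 3.31, then 3.54 and 3.49. For GlutTrans it was lowest in sample 2, 1.46 and 1.44, against 1.89 and 1.97 in wild type and 1.97 and 1.88 in sample 1. The 4 controls thus did not move together.

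The oleosin genes were lower in both transgenic samples. P91, an isoform of the 24 kDa oleosin, fell 16.9-fold, from 15.23 ± 0.16 to 11.15 ± 0.63 on the log2 scale (SD, n = 2 and 2; limma adjusted p = 0.0331). P89, the other isoform, fell 4.97-fold by its brightest probe set (log2 change -2.31, SE 0.22, adjusted p = 0.0428). Adjusted over the list alone, 2 of 2 genes passed, as they did over all probe sets tested. The probe sets of P89 did not move alike: the other bright probe set had a change of -1.79 (adjusted p = 0.0601) and the dim one, with wild type signals of 164 and 211, 0.39 (adjusted p = 0.627). The samples titled transgenic, including replicate 1 with its conflicting description, thus carried the lower P91 and P89 signals. The named oleosins are close in sequence, and probe sets may detect both. With wild type replicate 1 or 2 left out, or both averaged to 1 sample, no probe set on the array passed, the oleosins included; the spread then came from the transgenic pair alone. The change of P91 in those fits was -3.97, -4.19 and -4.08, and that of P89 was -2.22, -2.41 and -2.31.

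**Figure D1:**
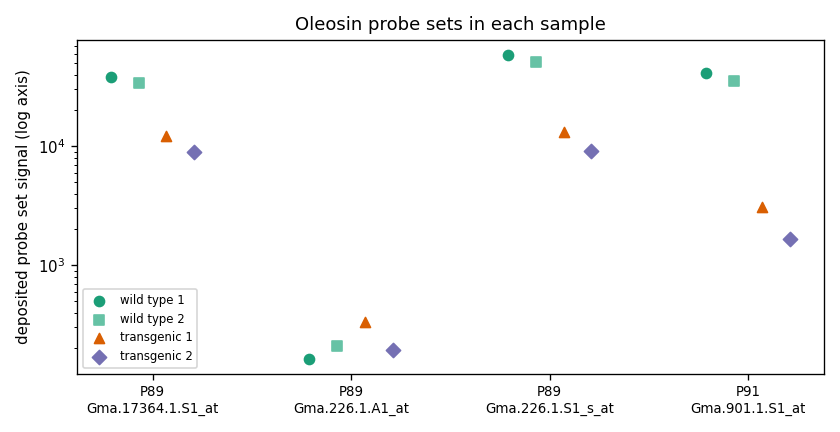
Deposited signal of the 4 oleosin probe sets (log axis) in each sample, with technical arrays averaged for the transgenic samples. Points are single samples. P91 read 41623 and 35590 in wild type and 3102 and 1662 in the transgenic samples.

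Across the array, HPS, a hydrophobic protein of the soybean seed surface, had the largest fitted fall among named genes past the threshold. It dropped from 12.25 ± 0.02 to background in both transgenic samples, at least 74.0-fold (n = 2 and 2, limma adjusted p = 0.00906). Other genes listed here also fell to background, and such bounds give no order. AGL1L fell at least 14.1-fold and GA2OX6, named for gibberellin 2-oxidases that inactivate gibberellins, at least 15.8-fold. LOC100790863 fell 35.5-fold and LOC100306479 fell 37.7-fold, while LOC100306605 fell at least 35.4-fold. LOC100801232, LOC100305999 and LOC100794412 fell as well, with log2 changes of -4.33, -4.32 and -4.31. Rises were smaller. SEOC rose 7.44-fold, LOC547583 (synonym GSTU18, a glutathione S-transferase) 5.86-fold, the transcription factor gene NAC2 4.74-fold and the seed maturation protein gene PM41 3.81-fold. LOC100783376, LOC100812481, LOC100500465, LOC732637, LOC100803175 and LOC100306608 rose between 4.40-fold and 6.93-fold.

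In all, 168 of 29574 probe sets passed, 54 higher and 114 lower, and 103 of them had no single gene name. Among 5415 genes 53 passed, 22 higher and 31 lower. GASA9 and GASA4, of a gibberellin-regulated family, fell 13.5-fold and 8.33-fold, and PRP2, a proline-rich protein gene chosen after its values were seen, had a log2 change of 1.54. The counts rest on the wild type pair: with wild type replicate 1 or 2 left out, or both averaged to 1 sample, limma called 0 probe sets, with 1177, 1251 and 1131 at an unadjusted p under 0.05. Without transgenic replicate 1 it called 11348, and without replicate 2, 5874.

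**Figure D2:**
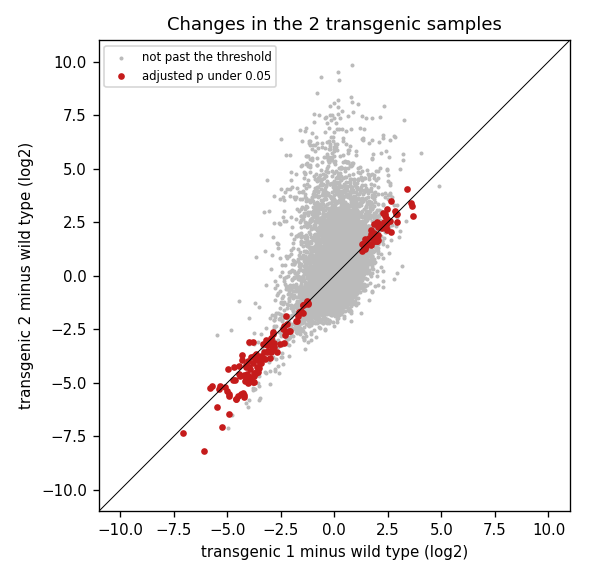
Log2 change from the wild type mean in transgenic sample 1 (horizontal) and sample 2 (vertical) for 29574 probe sets. Both axes share the wild type arrays, and the line marks equal change. Red points are the 168 past the threshold.

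Seed maturation genes, late embryogenesis abundant proteins among them, formed the list with the clearest shift. Its 31 genes had a median log2 change of 1.12 and 23 of them lay above both wild type arrays in both transgenic samples. PM41, PM32, PM25 and PM28 rose, by 1.93, 1.78, 1.58 and 1.41, and no gene fell. Adjusted over the list alone 22 rose. Camera gave an adjusted p of 3.27e-10, and the adjusted p = 0.524 with an estimated correlation. Fry, which tests a list without comparing it with other genes, gave adjusted p = 0.0302 for this list and for the seed coat markers, and from 0.0544 to 0.614 for the other 20 lists. GOLS, the galactinol synthase gene of raffinose sugar synthesis, had a change of 1.73 in sample 1 and 3.96 in sample 2 (adjusted p = 0.207). LEC1-A and WRI1B, regulators of seed filling, had changes of -1.16 and -0.67, and neither passed over all probe sets. Adjusted over the list alone, both passed, as did GOLS in its list of 1.

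HPS, whose transcript was not checked for a seed coat origin, also stood in the list of seed coat markers. Of its other members, SCB1, a seed coat BURP protein, had a change of -4.52 (adjusted p = 0.0650) and Ep, the seed coat peroxidase, had adjusted p = 0.181. The signal of Ep was 129 and 130 in wild type, 9.24 and 117 on the unlike technical arrays of transgenic sample 1, and 33.6 and 35.6 in sample 2. Over all probe sets 1 of 3 fell, and adjusted over the list alone 3 did. Camera gave an adjusted p of 0.00120, and the adjusted p = 0.610 with an estimated correlation. The source names call 1 wild type array cotyledon and the other seed, yet the wild type arrays read alike for HPS (4822 and 4901) and SCB1 (3713 and 3994). The list median, -4.52, became -1.42 with no filter on dim probe sets, which is the fitted value of Ep.

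Few storage and lipid genes passed. Of 11 storage protein genes BG7S-2 rose 3.53-fold and GY3, a glycinin gene, fell 6.66-fold. The others, GY2 (-0.39) and SBP2 (-0.56) among them, did not pass, and camera gave an adjusted p of 0.187. Several of these were very bright and read like bright genes of other lists. GY5, the inhibitor KTI3 and the lipoxygenase LOX1.1, chosen after their values were seen, had 63226, 62880 and 62192 on wild type array 1. In transgenic sample 2 they had 46847, 45384 and 45158. P89 read 58076 and 50977 in wild type. A ceiling of the signal near such values would hide or understate changes, and it was not tested for. None of 20 fatty acid and oil synthesis genes passed over all probe sets. ACCC-3 and ACCC-2, for the biotin carboxylase of acetyl-CoA carboxylase, had changes of -1.07 and -1.05, LOC548033 (synonym KAS III) -0.92 and ACCB-1 -0.83. Adjusted over the list alone 6 fell and 1 rose. The list median was -0.44 (camera adjusted p = 0.0222; adjusted p = 0.610 with an estimated correlation), and without transgenic replicate 2 it was -0.16 (adjusted p = 0.223). Of 9 protease inhibitor, lectin and allergen genes none passed (adjusted p = 0.427): KTI1 had a change of -0.40 and P34 -0.25, while KTI-2 had -0.07 in sample 1 and -1.05 in sample 2, and BBI-1 0.34 and 3.91.

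Chaperones of the endoplasmic reticulum had a median of -0.43 over 8 genes. PDIM-1, a protein disulfide isomerase gene, fell 2.37-fold, while BIP4 (-0.83), LOC100170705 (synonym PDIL-1, -0.83) and PDIL-2 (-0.44) did not pass. PDIL-2 had -0.70 in sample 1 and -0.19 in sample 2. Adjusted over the list alone 3 fell. In the photosynthesis list LOC547819 (synonym LHCP) fell 3.78-fold, and CAB3 (adjusted p = 0.129), ATPC (-0.93) and PSAD (-0.40) did not pass; adjusted over the list alone 2 of 10 fell. Of 9 lipoxygenases none passed over all probe sets and 4 fell when adjusted over the list alone, LOX9 (-3.58), VLXB (-1.80), LOX7 and LOXB1. LOX7 and LOXB1 lay at or under background in both transgenic samples, each at least 2.15-fold lower. Camera's adjusted p was 0.0122, 0.0174 and 0.00781 for the chaperones, photosynthesis and lipoxygenases, and the adjusted p = 0.610 for each with an estimated correlation. Without transgenic replicate 2 the photosynthesis and lipoxygenase lists had adjusted p = 0.183 and 0.125, and with the stricter filter the lipoxygenases had adjusted p = 0.124.

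Of 21 phenylpropanoid and isoflavone genes IFR1 fell to background, from signals of 372 and 402 in wild type (adjusted p = 0.0453). IFS1 (1.20), IFS2 (1.60) and CHS8 (2.85 in sample 1 and 6.47 in sample 2) did not pass over all probe sets; adjusted over the list alone 7 rose and 2 fell. Camera gave an adjusted p of 0.0122 (upward), and the adjusted p = 0.610 with an estimated correlation; the list median, 0.74, was 0.29 without transgenic replicate 2 and 1.69 without replicate 1. The ribosomal protein genes RPL37 (-0.55), RPS6 (-0.62), RPL2 (-0.49) and RPS13 (-0.32) did not pass; adjusted over the list alone 2 of 5 fell (camera adjusted p = 0.0488; adjusted p = 0.610 with an estimated correlation). Their list median of -0.49 became -0.24 without transgenic replicate 2 (adjusted p = 0.230), and the adjusted p was 0.119 and 0.0545 without wild type replicates 1 and 2 and 0.103 after quantile normalization; in all, the list passed in 10 of 18 alternative settings. No member passed, over all probe sets or over the list alone, in the heat shock, lipid breakdown, pathogenesis-related, autophagy and vacuolar processing, or reference lists, with camera adjusted p of 0.103, 0.322, 0.187, 0.412 and 0.412. The heat shock list had adjusted p = 0.0155 without wild type replicate 1 and 0.0407 with the wild type arrays averaged to 1 sample, and the lipid breakdown list 0.0170 without transgenic replicate 1. The pathogenesis-related list had 5.04e-05 (upward) without transgenic replicate 1 and 0.00814 (downward) without replicate 2. HSP90A1 had a change of 1.13 (0.67 in sample 1 and 1.59 in sample 2), HSP90-1 -0.46, HSP23.9 0.38 and HSP22.3 0.74 (1.05 and 0.44). VPE had 0.17, ATG6 0.08 (0.01 and 0.16) and ATG3A 0.05 (-0.12 and 0.21). GAPDH had -0.32, CYP2 -1.01, TUBB2 -0.37 (-0.10 and -0.65) and GAPC1 -0.23. VPE2 had -0.94 in sample 1 and 0.91 in sample 2.

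**Figure D3:**
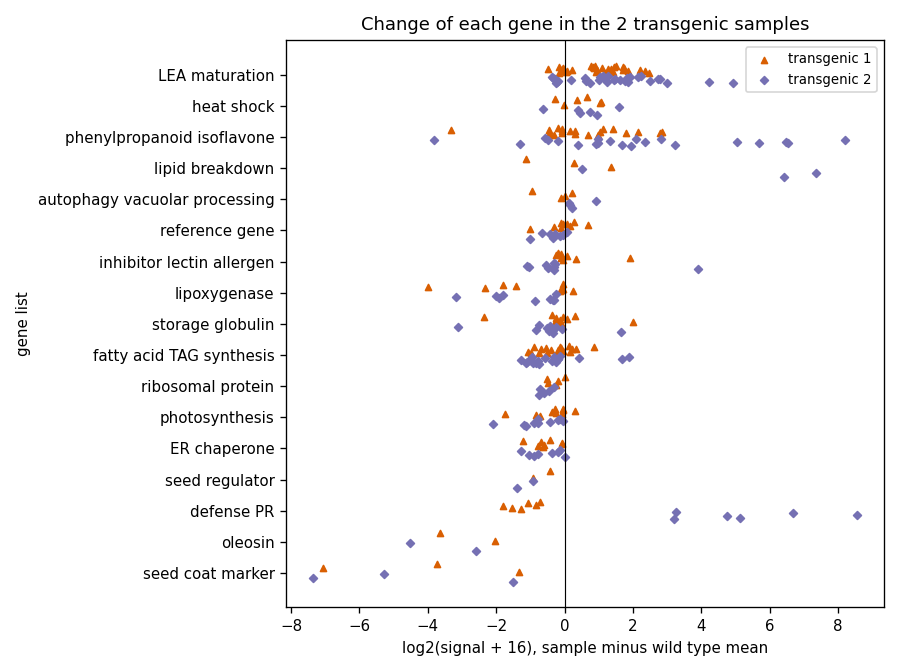
Change of each gene from the wild type mean (log2 scale, horizontal) by gene list, in transgenic sample 1 (triangles) and sample 2 (diamonds). The 31 seed maturation genes have a median of 1.09 in sample 1 and 1.28 in sample 2, and the 6 pathogenesis-related genes -1.17 and 4.95.

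The transgenic samples differed strongly from each other. All 6 pathogenesis-related genes were higher in sample 2, with a median difference of 6.62 log2 units; PR-10 was at least 360-fold higher (limma adjusted p = 1.84e-11) and PR1-7 at least 69.3-fold. The glyoxylate cycle genes ICL1 and MS were higher, ICL1 33.1-fold and MS with signals of 5910 and 6034 against 2.95 and 85.5 on the technical arrays of sample 1. Among phenylpropanoid and isoflavone genes 14 of 21 were higher and 4 lower, with IFR at least 88.4-fold and CHS8 12.3-fold higher. The rule took PR-10, LOC100500525, GSTU42, LOC547527 and IFR as rises by the fitted values, which for all but LOC547527 rest on sample 1 signals at background and give no order. The largest falls by the fitted values were those of LOC547541, LOC100803418, LOC100127401 and LOC100782951, between 5.47-fold and 7.66-fold, and of LOC100793648, which was at background in sample 2 and at least 2.31-fold lower. In total 12730 of 29574 probe sets differed, 4610 higher and 8120 lower in sample 2, and of those over 4-fold 1170 were higher and 64 lower. Camera gave adjusted p of 1.02e-04 for the pathogenesis-related and 0.00111 for the phenylpropanoid list, and the adjusted p = 0.310 for both with an estimated correlation. The test compares these samples only, with technical error.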

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

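The tests of explanations below were all chosen after the results were seen. Probe sets outside the comparison that were brighter on all 4 transgenic arrays than on both wild type arrays, with a transgenic mean at least 2-fold higher, came from the controls and, among the brightest, from pathogen sequences. Among control probe sets AFFX-Gma-AJ002682-2_s_at was 6.16-fold higher, AFFX-Gm_P450_M_s_at 3.14-fold, AFFX-Gm_P450_5_s_at 3.11-fold, AFFX-Gm_P450_3_s_at 2.41-fold and AFFX-Gm_GlutTrans_5_s_at 2.25-fold. The fold of AFFX-Gma-AJ002682-2_s_at is uncertain, since its wild type signals of 18.1 and 63.1 lay on either side of the background cutoff of 49.9. Among pathogen probe sets a pair from Heterodera glycines was 5.86-fold and 2.25-fold higher. The second of the pair read 653 and 349 in wild type. It read 1169 and 2700 on the technical arrays of transgenic sample 1, and 678 and 673 in sample 2. From Phytophthora sojae PsAffx.psHB015xB20f_at was 3.63-fold and PsAffx.psHB026xH01f_s_at 2.05-fold higher. Over the 23350 pathogen probe sets 76 were higher and 302 lower by this measure.

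The seed coat list had a median of -4.52, though 1 of 3 genes, HPS, passed over all probe sets; SCB1 and Ep had adjusted p = 0.0650 and 0.181, and the list adjusted p = 0.610 with an estimated correlation. The scaling of the arrays is argued against, since that median was -4.52 after quantile normalization. Less seed coat tissue in the transgenic extracts may account for part or all of it. It would lower the markers alike if seed coat were their only source of signal. HPS fell by at least 2.47 and 0.92 log2 units more than SCB1 in samples 1 and 2. The mean excess (1.69) was above the SD of the 2 values and the smaller value under it. That SD cannot judge the excess. HPS lay at background and was counted at the cutoff, so the SD holds only the difference of SCB1 between the samples. Both values are lower bounds, and the technical arrays of SCB1 read 272 and 273, then 81.0 and 84.3. For HPS and SCB1 this argues against an equal fall. It does not decide on less tissue, because signal of either marker from other tissue or from cross-hybridisation was not measured. Less tissue thus stays open, and Ep was too near background to compare. An effect of the construct, or another seed source, stays open and was not tested.

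The seed maturation list was shifted upward, with a median of 1.12, though 4 of 31 genes passed, 6 had values below wild type and the adjusted p = 0.524 with an estimated correlation. Scaling of the arrays is argued against, since the median rise was 1.18 after quantile normalization. Transgenic seeds further along in maturation than wild type seeds are a candidate explanation. Of the 2 other list medians that it predicts to be lower, photosynthesis (-0.48) and seed regulators (-0.92), 2 lay below 0. A fall like that of photosynthesis was not particular to the predicted lists. The ribosomal protein, fatty acid and chaperone lists had medians of -0.49, -0.44 and -0.43, while other lists, such as heat shock (0.60), were higher. The photosynthesis median was -0.27 in sample 1 and -0.78 in sample 2, and camera gave adjusted p = 0.610 with an estimated correlation. The regulator list holds 2 genes and neither passed over all probe sets. A later stage cannot be told apart from an effect of the construct, because the labels give no seed stage and the stage would follow the groups.

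Of 30 genes of the pathogenesis-related, phenylpropanoid and isoflavone, and lipid breakdown lists, 23 were higher and 4 lower in transgenic sample 2 than in sample 1, with a median difference of 2.33 log2 units; with an estimated correlation the lists had adjusted p = 0.310, 0.310 and 0.537. Variation between arrays of one extract is argued against, since technical arrays differed by at most 0.0192 in that median. A later maturation of sample 2 was tested by asking the seed maturation list to differ by a set share of 2.33. It differed by 0.12 and fell short, with members going both ways, 14 higher and 8 lower. The photosynthesis and seed regulator lists, which later maturation predicts to be lower, were lower in sample 2, with median differences of -0.37 and -0.49. Lists outside that prediction were lower too: reference genes (-0.24), ribosomal proteins (-0.24), storage proteins (-0.26) and aquaporins (-0.44). The WRKY, NAC and GST lists were higher. The falls are thus not particular to the predicted lists and do not decide, and a later maturation of sample 2 stays open. The 3′ to 5′ ratios of SucBP and actin were highest in sample 2 and that of GlutTrans lowest, and RNA quality was not tested as an explanation. Stress, infection or handling of the seeds behind sample 2 stays open and was not tested.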

How the results depend on the processing

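The alternative with the wild type arrays averaged to 1 sample was chosen after seeing the data. The calls depend on how the spread is estimated. The 168 calls (54 higher, 114 lower) became 2069 (826 and 1243) with 6 arrays as separate samples, 1100 (510 and 590) with the biological sample as a random block, and 42 (0 and 42) without the trend; 15 had an adjusted p under 0.01. Leaving out each sample gave from 0 to 11348 calls, from 0 to 4435 higher and from 0 to 6913 lower. With the wild type arrays averaged to 1 sample there were 0 calls, 0 higher and 0 lower. A sample left alone in its group is assumed to vary like the other group. Every one of the 168 kept its sign in each alternative in which it was tested. For all 168 both transgenic samples lay outside the wild type range on the same side. Leaving out or averaging samples could therefore not change a sign. Replicate numbers did not pair samples (r = -0.04 across probe sets, which are not independent), and the replicate block gave 140 calls, 119 of them shared. The 2 oleosin calls became 0 without the trend, 0 with the wild type arrays averaged and 1 with technical replicate 1 arrays alone, and ranged from 0 to 3 with a sample left out. The 8 fixed lists past the threshold became 5 with the stricter filter and 0 with an estimated correlation, which 2 residual degrees of freedom estimate poorly, and ranged from 5 to 10 with a sample left out. The pathogenesis-related list had a median of -1.17 and 4.95, OLPa a change of -1.54 and 5.14, and VPE2 a change of -0.94 and 0.91, without transgenic replicates 2 and 1 in turn; the transgenic samples lay on opposite sides of wild type. The 12730 differences between transgenic samples ranged from 12430 to 13157. Other causes were not tested. Signal over background limits HPS and other genes at the cutoff to bounds.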

Other observations

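Families added after the annotation was seen, and before values were, moved as follows. Of 21 genes whose symbols begin with GST none passed over all probe sets and 18 had values above wild type, with a median log2 change of 0.87; LOC547583 (synonym GSTU18), which passed, is not among them by its symbol. GSTU27, at background in wild type, was at least 11.6-fold higher (adjusted p = 0.0757), and GST24 had a change of 1.25, GSTa 0.87 and GSTF7 -0.85. The median was 0.36 without transgenic replicate 2 and 1.30 without replicate 1. Camera gave an adjusted p of 0.00434, and the adjusted p = 0.610 with an estimated correlation. Of 40 WRKY transcription factor genes none passed, with a median of 0.87 and WRKY4 at 0.72 (adjusted p = 0.00314; adjusted p = 0.610 with an estimated correlation); the median was 0.30 without transgenic replicate 2, where the list did not pass. NAC2 alone passed among 13 NAC genes (list median 0.95, adjusted p = 0.0269; adjusted p = 0.610 with an estimated correlation). Without transgenic replicate 2 that median was 0.24 (adjusted p = 0.717), and without wild type replicate 2 the adjusted p was 0.0545. GASA9 and GASA4 fell among 14 GASA genes (list median -0.33, adjusted p = 0.0122; adjusted p = 0.610 with an estimated correlation), and without transgenic replicate 2 that median was -0.09 (adjusted p = 0.337). Of 46 MYB, 48 bZIP and 18 aquaporin genes none passed, with list adjusted p of 0.0329, 0.184 and 0.0907; the first had adjusted p = 0.610 with an estimated correlation. The MYB list had adjusted p = 0.173 without transgenic replicate 2, 0.0514 without transgenic replicate 1 and 0.0545 without wild type replicate 2, and passed in 13 of 18 alternative settings. The aquaporins had 0.00830 without transgenic replicate 1 and passed in 2 of 18.

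Between the transgenic samples, 25 of 40 WRKY genes, 10 of 13 NAC genes and 14 of the 21 GST genes were higher in sample 2, with 5, 0 and 3 lower. Their medians differed by 1.33, 2.45 and 0.83 log2 units. SSTP-1 and the sugar transporter gene SWEET24, chosen after their values were seen, were 4.35-fold and 4.22-fold lower in sample 2 than in sample 1. Their signals were 12812 and 12532, and 9609 and 9503, in wild type, against 392 and 575 in transgenic sample 1.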
